A study of Mus musculus with 128 samples.

How the data were processed

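RNA was measured by sequencing in 8 tissues of mice at 4 ages, with 4 libraries per tissue and age and 128 libraries in all. Libraries were made with the Illumina Stranded mRNA Prep from RNA extracted with RNAiso Plus, per the labels' protocols. FastQC, STAR, RSEM and DESeq2 are named without versions, with the build GRCm39, per the submitters' processing notes. The annotation is not given in the sources used here. The authors deposited a table for each tissue, with 55285 gene symbols and a column of signal per library, normalised within that table. In every library 100% of the deposited values are whole numbers of reads, within a tolerance of 0.01 reads (largest deviation 0.0017), once multiplied by a single factor for that library, which returns the reads behind the values. No sample column was left unused.

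Each tissue was normalised separately by the authors, so tests of age were made within a table, and differences between tissues are differences of within-table changes. The design written before the data were examined assumed read counts and named edgeR as the main test. Because the files hold normalised values, limma-trend on log2(value + 1) took its place, and camera was run on that scale in place of log2 CPM. edgeR and DESeq2 on the recovered reads were run as alternatives, and the number of genes each calls is given in the closing section. The comparisons, gene lists, panel genes, rule for named genes and most alternatives were likewise set before the data were examined.

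For each tissue a model with 1 mean per age was fitted to all 16 libraries in limma 3.58.1 (R 4.3.3), with eBayes trend and genes kept by filterByExpr of edgeR 4.0.16 at a minimum count of 10. Tests were two-sided and adjusted by Benjamini-Hochberg over the genes of that tissue, with 0.05 as the threshold. Between 14280 (Heart) and 17112 (Lung) genes were tested. The genes named are, in each tissue, the 8 highest and 8 lowest log2 fold changes at 30 against 6 months among genes past the threshold with a mean of 50 or more reads per library and no overlap between the 4 and the 4 libraries. To these were added 10 panel genes, the members of a list with the smallest adjusted p in the list's direction as examples, and the 10 genes past the threshold in most tissues. Genes with Gm or Rik symbols and immunoglobulin variable, diversity and joining segments were left out of the 8 highest, the 8 lowest and these last 10. Genes with near-identical copies, such as the H2-Q, Mup, Hspa1, Amd and Ighg genes, can exchange reads. Some withheld genes are not reported here and were left out of the search for single libraries that stand apart.

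Gene lists, 63 in number, were tested with camera at its preset correlation of 0.01 over lists with 5 or more tested members, and again with an estimated correlation. Members past the threshold were counted over all genes tested and adjusted over the list alone. Genes shared between tissues were counted over 11817 genes tested in all 8 tissues and set against 10000 random draws within 10 bins of expression. Differences between tissues in the change from 6 to 30 months were tested by a limma-trend F test on log2(value + 1) of all libraries, over 21683 genes, in place of the edgeR quasi-likelihood test of the design, which was run as an alternative. Libraries were checked for copies (lowest chi-square per degree of freedom between replicates 2.48, so none) and for their median Spearman correlation with the other libraries of the tissue.

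The alternatives were edgeR with RLE, DESeq2 1.42.0, limma-voom with quality weights, no filter on low values, a fit of the 2 ages compared alone, the replicate number as a block, pseudocounts of 0.1 and 5, and leaving out each library in turn. Alternatives chosen after seeing the data were edgeR with TMM, limma-trend on reads scaled by TMM, the pseudocounts for the gene counts and lists at 15 and 24 months. So was leaving out any of the 4 libraries that stood apart where it was of neither age compared, or 2 of them together. Leaving out 1 library for the shared genes and the genes that differ between tissues was chosen afterwards too. Tables were handled with the package data.table, version 1.17.8, and pandas 2.3.3, and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

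Recovered depth ran from 7.65 to 82.8 M reads. The tests were tested on simulated data with the real levels and spread of each tissue, in which 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold in each comparison. Of genes changed 1.5-fold, 14.9% (Liver, 24 months, 14304 genes tested) to 71.6% (Brain, 30 months, 16883 genes tested) were called. Of genes changed 2-fold it was 46.3% (Skin, 24 months, 16883 genes tested) to 89.6% (Brain, 30 months), and of genes changed 4-fold 83.3% (Liver, 30 months) to 98.5% (Heart, 30 months, 14280 genes tested). Of the calls 1.32% to 8.28% were false. The simulated genes vary independently of each other, while a split of the real libraries that mixes 2 ages called up to 1798 genes (Skin, 24 months). This rate of false calls therefore need not hold for the real libraries. A list raised 1.5-fold was called in all 8 tissues and 0 of 20 unchanged lists in any, while splits of the real libraries that mix the 2 ages called up to 25 to 32 lists per tissue, so the simulated rate of false list calls does not carry over to real lists. For the sharing test 200 genes were changed 4-fold in all 8 tissues. It found 201 genes, of which 200 were those changed, with at most 21 in the draws. Between tissues 49.3%, 85.1% and 100% of genes changed 1.5-fold, 2-fold and 4-fold were called out of 11817 tested. Of 200 genes changed alike in all tissues 5 were called. On the real libraries, splits that mix the 2 ages alike in every tissue called up to 724 of 21683 genes in that test. The simulated share of 5 in 200 therefore need not hold for the real libraries.

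Replicates are single libraries, and the labels do not say whether tissues with the same age and number come from the same animal.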

Results

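Messenger RNA was sequenced from 8 tissues of male wild-type C57BL/6J mice at 6, 15, 24 and 30 months of age: aorta, brain, heart, kidney, liver, lung, gastrocnemius muscle (called Muscle here) and skin. Each tissue and age had 4 libraries, which makes 128 libraries in 32 groups. The Aorta records carry the age in the title alone and name no sex or strain. Library depth, recovered from the tables, ran from 7.65 M reads (Heart, 24 months, replicate 4) to 82.8 M (Liver, 15 months, replicate 1), with a median of 15.6 M. By tissue it ran from 12.5 to 35.6 M in Aorta, 10.1 to 35.99 in Brain, 7.65 to 20.2 in Heart, 11.9 to 23.3 in Kidney, 10.1 to 82.8 in Liver, 11.8 to 21.3 in Lung, 12.3 to 23.8 in Muscle and 11.8 to 17.4 in Skin. The comparisons ask how each tissue at 15, 24 and 30 months differs from the same tissue at 6 months, which changes recur between tissues, and which differ between them. Changes are log2 fold changes against 6 months ± SE, with 4 libraries per age, and adjusted p is limma-trend's two-sided Benjamini-Hochberg value over the genes tested in that tissue. The words rose and fell are used of genes with an adjusted p under 0.05. List tests are camera with a preset correlation, and each list was fixed before the data were examined.

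**Figure D1:**
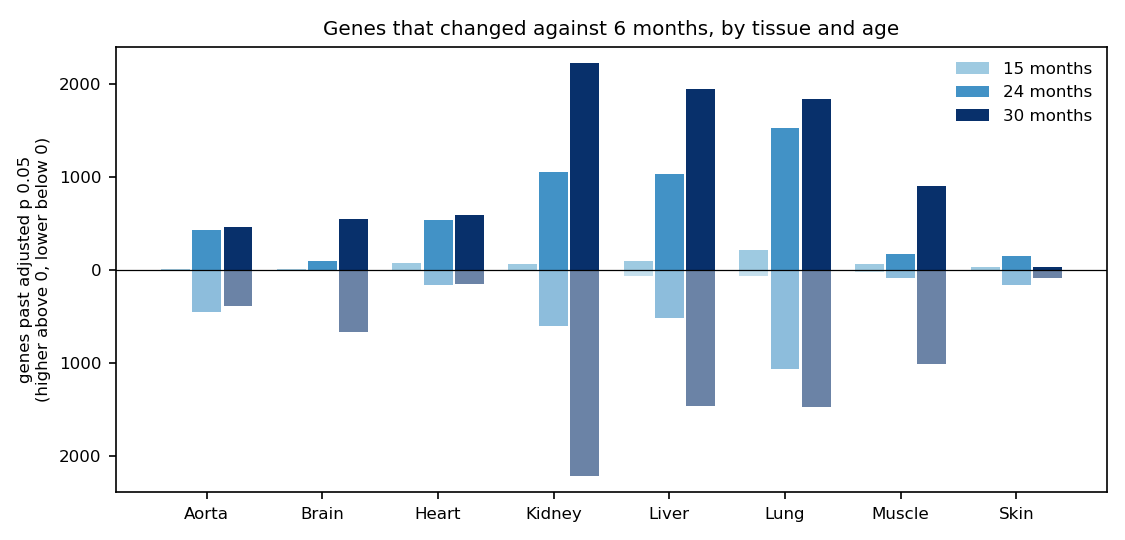
Number of genes higher (up) or lower (down) than at 6 months with an adjusted p under 0.05, by tissue, at 15, 24 and 30 months. Bars are counts over 4 libraries per age. At 30 months the bars up and down together hold 4431 genes in Kidney (2216 and 2215) and 3408 in Liver (1939 and 1469). They hold 3316 in Lung (1837 and 1479), against 122 in Skin (28 and 94).

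The immune genes Gpnmb, C4b and Igkc each rose in 6 of the 8 tissues at 30 months, in some of them close to the threshold. Gpnmb, a membrane glycoprotein of lipid-laden macrophages, rose in Brain, Heart, Kidney, Liver, Lung and Muscle, by 1.34 in Lung up to 5.54 in Liver. C4b, which encodes complement component 4, rose in the same 6 tissues, by 0.48 in Liver up to 2.88 in Heart. Igkc, the immunoglobulin kappa constant region, rose in Aorta, Brain, Kidney, Liver, Lung and Muscle, by 1.95 in Brain up to 4.15 in Liver. In Muscle its adjusted p was 0.0493, with 487.2, 402.5, 26.41 and 2149 normalised reads at 30 months against 14.82 to 134.6 at 6. The collagen genes Col1a1 and Col3a1 went the other way where they passed: Col1a1 fell in Lung (-1.13), Muscle (-2.23) and Skin (-2.48), and Col3a1 fell in Aorta, Brain, Lung and Muscle, by -0.70 to -2.30. Calls that fell short when 1 library was left out were those of Igkc in Muscle (any but 6-month replicate 1 or 30-month replicate 3, adjusted p up to 0.14) and Aorta (6-month replicate 1 or 2 or 30-month replicate 1, 3 or 4, up to 0.095), Gpnmb in Lung (6-month replicate 1, 2 or 4 or 30-month replicate 2, up to 0.0733) and C4b in Liver (any but 30-month replicate 3 or 4, up to 0.108). The same held for Col1a1 in Skin (6-month replicate 1 or 30-month replicate 3 or 4, up to 0.0525) and Col3a1 in Aorta (6-month replicate 2 or 3 or 30-month replicate 1, 3 or 4, up to 0.0919) and Brain (any but 30-month replicate 2 or 4, up to 0.0914).

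Of 11817 genes tested in all 8 tissues, 846 changed in the same direction in 3 or more tissues at 30 months, 583 of them higher and 264 lower (1 gene did both). Random draws that kept each tissue's number of calls and expression level gave a mean of 289.9 genes and at most 347 in 10000 draws (permutation p = 1e-04, one-sided, the smallest these draws can give). Genes higher in 3, 4, 5 and 6 tissues numbered 285, 169, 76 and 53, those lower 232, 23, 7 and 2, and no gene passed in 7 or 8. Ranked by number of tissues and mean size of change, the 10 leading genes were Igkc, Zbp1, Gpnmb, Ly9, H2-Q6, Ms4a6d, Lilrb4b, Apol9b, Tlr13 and H2-Q7. Zbp1, a sensor of Z-form nucleic acid induced by interferon, rose by 1.84 in Kidney to 3.34 in Heart. H2-Q6 and H2-Q7, class I histocompatibility genes with near-identical sequences that can share reads, rose by up to 3.30 and 2.88 in Brain. Tlr13, a Toll-like receptor of endosomes, rose by 0.98 in Brain to 2.76 in Liver. The tissues may come from the same mice, so they are not independent of each other, and asking for 4 or more tissues in place of 3 leaves 330 genes.

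The test of the difference itself (limma-trend F test on all libraries) found that the change from 6 to 30 months differed between tissues for 6925 of 21683 genes (31.9%). It included 15 of 18 genes looked at by name, such as C4b (adjusted p = 2.51e-18), Gpnmb (7.65e-14), Col1a1 (1.65e-09), B2m (1.5e-06), Cd74 (9.59e-06) and Cdkn1a (0.000109). Cdkn1a, the p21 inhibitor of the cell cycle, rose in Heart (0.93), Kidney (1.62), Liver (1.72), Lung (0.70) and Muscle (2.13), while its values were -0.02 in Aorta, 0.08 in Brain and 0.07 in Skin. When 1 library was left out, its limma-trend call within a tissue fell short in 5 of 8 fits in Lung (adjusted p up to 0.135). The same held for 4 of 8 fits in Liver (up to 0.0653) and 1 of 9 in Heart (0.0529). Tlr13 (adjusted p = 0.0522), Jchain (0.067) and Cdkn2a (0.231) did not pass. This F test covers all 8 tissues, while in the fits within tissues Cdkn2a passed the expression filter in 3 alone. With limma-voom and libraries of the same age and number treated as a block, 9 of the 15 genes passed. The 6 that did not were Igkc (adjusted p = 0.268), Zbp1 (0.34), H2-Q6 (0.0571), Ms4a6d (0.11), Lilrb4b (0.0736) and Apol9b (0.15). The correlation estimated within these blocks was 0.0141. Both the test and the block differ from the limma-trend F test, and which of them cost the 6 calls was not tested.

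**Figure D2:**
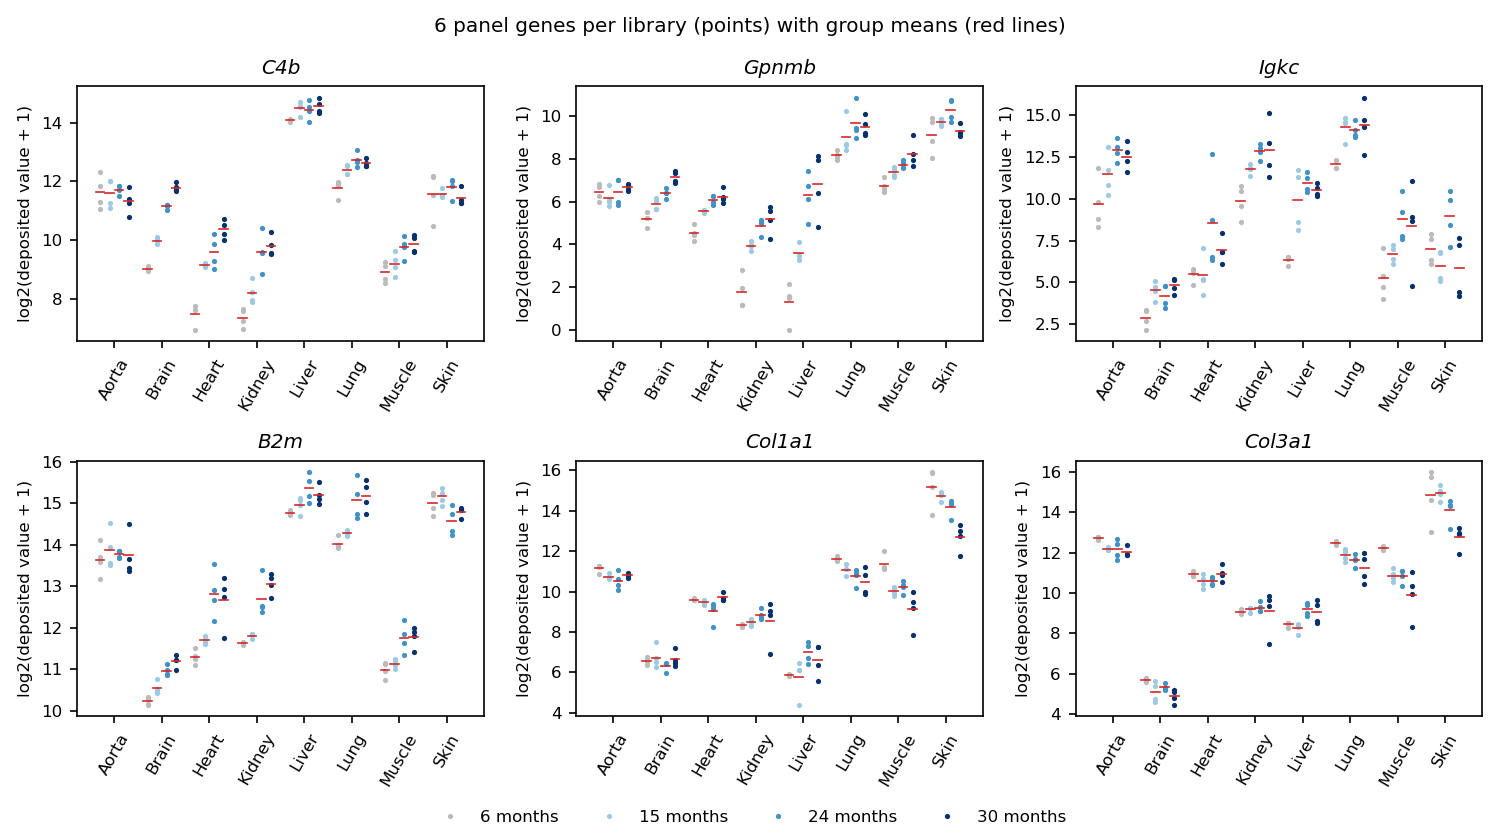
Level of 6 genes in each library, as log2 of the deposited normalised value plus 1, by tissue and age; points are single libraries (4 per group) and red lines are group means. C4b in Brain moves from a mean of 520.5 at 6 months to 3554 at 30 months with no overlap, while Col1a1 in Muscle moves from 2713 to 633.7.

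**Figure D3:**
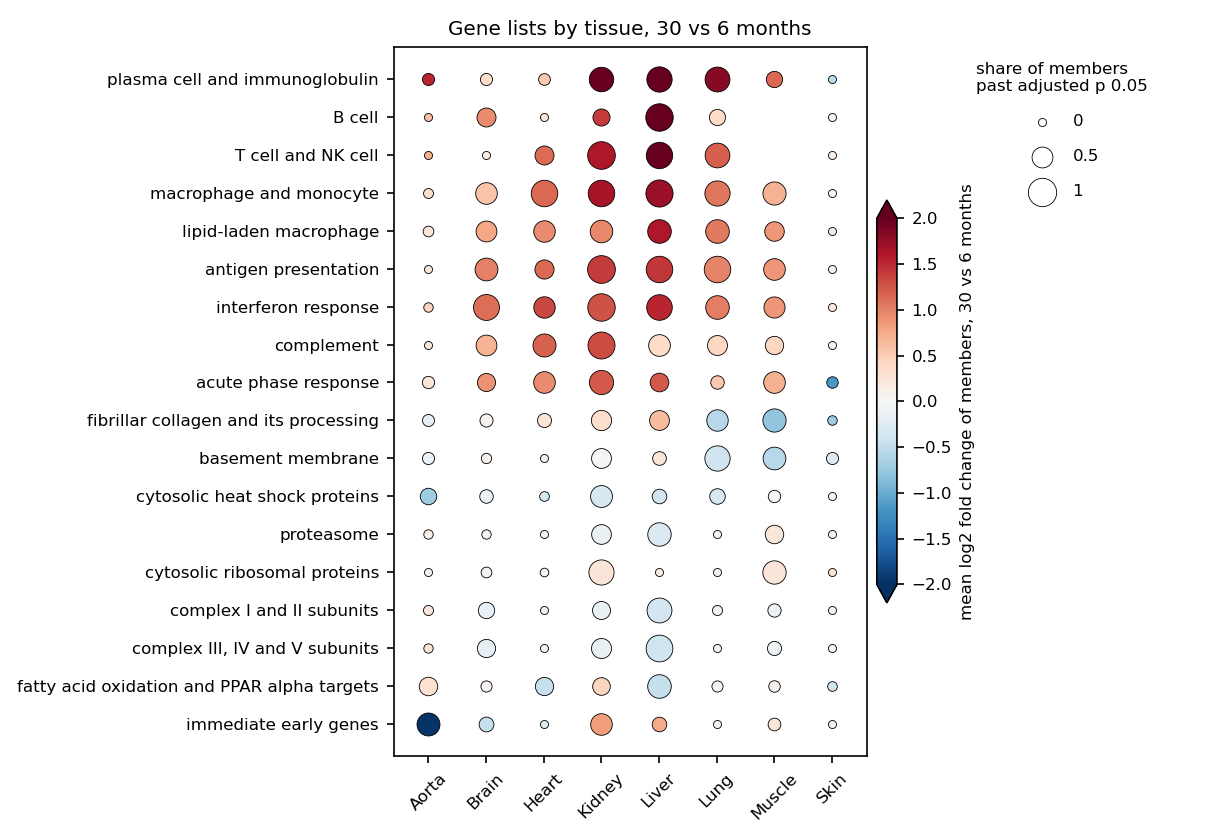
Gene lists at 30 against 6 months by tissue: colour is the mean log2 fold change of the tested members, and point size grows with the share of them past an adjusted p of 0.05; a list with fewer than 5 tested members has no point. In Kidney 28 of 30 interferon genes rose, in Liver 14 of 15 B cell genes, and in Muscle 18 of 28 collagen genes fell (limma-trend).

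The Brain comparison asks what ageing changes in nervous tissue, and glial and immune genes led it. C4b was 2.77 ± 0.07 higher at 30 months (adjusted p = 1.14e-16), Serpina3n, an inhibitor of serine proteases made by reactive astrocytes, 1.83 ± 0.09 (2.85e-11), and Gfap, the filament protein of astrocytes, 1.32 ± 0.07 (9.08e-11). Microglial genes rose as well: Clec7a by 4.36 ± 0.50 (2.95e-05), Cst7 by 3.36 ± 0.39 (3.18e-05) and Lyz2 by 1.76 ± 0.12 (1.97e-08). Among the genes that fell were Gpr17, a receptor of committed oligodendrocyte precursors, at -0.88 ± 0.12 (0.000108), and the activity-regulated transcription factor genes Egr2 (-1.41 ± 0.37, 0.024) and Egr4 (-1.02 ± 0.15, 0.000416). Arc, a synaptic gene induced by neuronal activity, fell by 1.06 as well (adjusted p = 0.0395). When 1 library was left out, Arc missed the threshold in 7 of 8 fits (adjusted p up to 0.138) and Egr2 in 4 of 8 (up to 0.0869).

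Of 28 interferon genes tested in Brain, 23 rose and 0 fell (27 rose adjusted over the list alone; camera adjusted p = 1.3e-25), with Oasl2 at 1.59. Rises were also counted for 13 of 21 antigen presentation genes (19 adjusted over the list alone), 12 of 22 macrophage genes (19), 9 of 18 complement genes (11), 13 of 23 microglia genes (13) and 8 of 19 astrocyte genes (8), while 5 of 18 genes of oligodendrocyte precursors and neurogenesis fell (6). Camera's adjusted p for these 6 lists ran from 4.03e-20 to 0.000116, and all of them and the interferon list passed with an estimated correlation (adjusted p = 0.0129 to 0.0254). Subunits of the respiratory chain fell: 11 of 40 in complexes I and II (18 adjusted over the list alone, camera adjusted p = 1.27e-10) and 12 of 33 in complexes III to V (20, 1.39e-12), with Ndufa13 at -0.49 and Uqcr11 at -0.54. These respiratory calls were lost with an estimated correlation (adjusted p = 0.315 and 0.269). Synaptic genes such as Syp (-0.18) and Dlg4 (-0.21) were among 6 of 29 neuronal genes that fell (8 adjusted over the list alone, camera adjusted p = 0.00185, and adjusted p = 0.116 with an estimated correlation).

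In Brain 1215 of 16883 genes passed at 30 months (545 higher, 670 lower), 107 at 24 months (94 higher, 13 lower) and 4 at 15 months. The 4 at 15 months, named here after their values were seen, were C4b (0.95), Cd74 (0.92), Lyz2 (0.75) and Nlrp5-ps (1.95), all higher. C4b then stood at 2.12 at 24 months, Serpina3n at 0.98 and B2m, the light chain of class I molecules, at 0.74. The 15-month count ran from 1 to 7 when 1 library was left out (1 without 15-month replicate 3, 7 without 15-month replicate 1), and another way of splitting those 8 libraries called 195 genes. The 24-month count was 69 without 6-month replicate 4, 57 without 24-month replicate 1 and 69 without 24-month replicate 4, and fits of the 2 ages alone gave 2, 146 and 735 genes at 15, 24 and 30 months, and limma-voom 3, 150 and 1091.

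The Heart comparison showed higher complement and macrophage genes, whose lists passed with an estimated correlation, beside some lower fatty acid oxidation genes, whose list did not (adjusted p = 0.0604). At 30 months the monocyte chemokine gene Ccl8 was 4.44 ± 0.41 higher (adjusted p = 9.51e-06), Cfb, complement factor B, 3.40 ± 0.32 (9.65e-06), C4b 2.88 ± 0.23 (5.08e-06) and Vsig4, a complement receptor of resident macrophages, 2.58 ± 0.24 (9.51e-06). The long non-coding RNA Snhg11 rose by 3.77 ± 0.28 (3.13e-06). Pdk4, the kinase that restrains pyruvate dehydrogenase, fell (-1.18 ± 0.24, 0.00791), and so did Casq1, a calcium-binding protein of the sarcoplasmic reticulum (-1.46), and Aplnr, the apelin receptor (-1.04).

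In Heart 19 of 22 macrophage genes rose (22 adjusted over the list alone, camera adjusted p = 9.93e-27), with Cd68 at 1.14 and Mpeg1 at 1.64, and so did 12 of 19 complement genes (16, 3.06e-20), with C3 at 1.29 and C1s1 at 0.79. Both passed with an estimated correlation (adjusted p = 0.0161 and 0.0118). Interferon genes rose in 16 of 30 cases (30 adjusted over the list alone, 8.4e-24), antigen presentation genes in 9 of 22 (17, 2.98e-14) and cardiac stress genes in 6 of 19 (6, 1.77e-06). For these 3 lists the adjusted p was 0.105, 0.185 and 0.112 with an estimated correlation. The cardiac stress members that rose include the matrix genes Postn (1.60), Tnc (1.53) and Comp (1.09) and the protease inhibitor Timp1 (1.96). Fatty acid oxidation and PPAR alpha target genes fell in 8 of 22 cases (14 adjusted over the list alone, camera adjusted p = 4.92e-13), with Hadha at -0.55 and Slc25a20 at -0.39. That call gave an adjusted p = 0.0604 with an estimated correlation.

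Heart had 737 of 14280 genes past the threshold at 30 months (588 higher, 149 lower), 703 at 24 months (536 higher, 167 lower) and 84 at 15 months (72 higher, 12 lower). C4b was 1.68 higher at 15 and 2.11 at 24 months, and Gpnmb 1.03 and 1.58. The 24-month replicate 4 library stood apart from the other 15, with a median rank correlation of 0.914 and 235330 normalised reads on mt-Nd6 against 1198 to 2205 elsewhere. Without it the counts were 544 at 15 months (353 higher, 191 lower), 1157 at 24 (717 higher, 440 lower) and 2209 at 30 (1204 higher, 1005 lower). When the 2 ages alone were fitted the counts were 635 at 15, 99 at 24 and 2100 at 30 months, and limma-voom gave 745, 1229 and 2181. The 30-month count was 454, 378 and 452 without 6-month replicate 3, 30-month replicate 1 and 30-month replicate 3, the 24-month count 358 to 396 without any 1 of the 6-month libraries, and the 15-month count 35 to 55 without 6-month replicate 1, 2 or 4 or 15-month replicate 2 or 4.

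**Figure D4:**
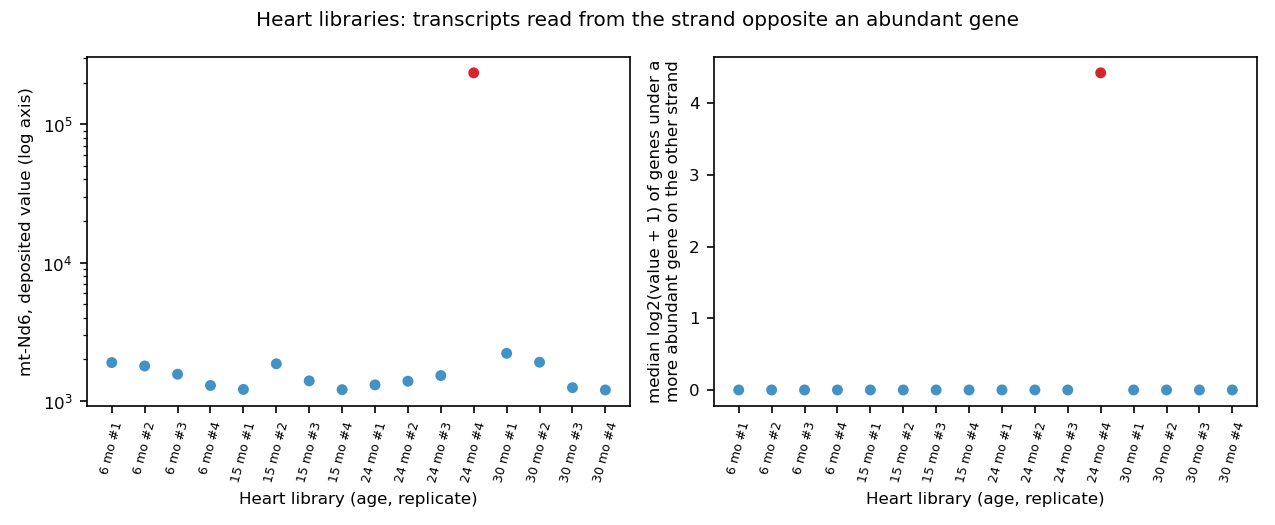
For each of the 16 Heart libraries, the normalised reads on mt-Nd6 (log axis) and the median log2 level of 56 genes that lie under exons of a far more abundant gene on the opposite strand. The 24-month replicate 4 library reaches 235330 reads and a median of 4.42, and the other 15 lie between 1198 and 2205 reads with a median of 0.

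The Kidney comparison showed higher tubule injury genes at 30 months, whose list passed with an estimated correlation, beside higher leukocyte genes, whose lists did not. Cxcl13, a chemokine that attracts B cells, rose by 4.88 ± 0.51 (adjusted p = 9.9e-06) and the immunoglobulin heavy chain gene Ighg1 by 5.50 ± 1.04 (0.00115), although reads can be shared among the Ighg genes. Lcn2, an iron-carrier protein made by injured tubules, rose by 3.18 ± 0.20 (1.82e-07), Vcam1 by 1.94 ± 0.14 (4e-07) and C3 by 2.91 ± 0.24 (9.79e-07). The solute carriers Slco1a1 and Slc22a7, which take up organic anions, fell (-3.30 ± 0.78, 0.00508, and -3.04 ± 0.55, 0.000853). Acsm3, an acyl-CoA synthetase of the proximal tubule, fell by 2.42. Without 30-month replicate 3, which stood apart for Slco1a1, these 3 genes stood at -2.20, -2.15 and -1.73.

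Counts of genes that rose in Kidney were 13 of 18 for plasma cells and immunoglobulins (14 adjusted over the list alone), 18 of 19 for T and NK cells (19), 19 of 22 for macrophages (21), 21 of 22 for antigen presentation (21), 28 of 30 for interferon response (28) and 17 of 20 for complement (17, with 1 lower). Camera's adjusted p lay between 1.03e-17 and 2.93e-06 for these lists, and the adjusted p lay between 0.0583 and 0.257 with an estimated correlation. Tubule injury genes rose in 18 of 24 cases (21 adjusted over the list alone, camera adjusted p = 1.24e-13) and passed with an estimated correlation (adjusted p = 0.0129). So did the p53 targets, where 8 of 22 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.000573, and 0.0285 with an estimated correlation), among them Cdkn1a (1.62), Eda2r (1.66) and Phlda3 (0.85). Ribosomal protein genes rose in 57 of 74 cases (65 adjusted over the list alone, 6.82e-16), while 11 of 26 proximal tubule genes fell and 1 rose (12 and 2, 0.00196) and 7 of 13 genes of the mitochondrial genome fell (7, 0.000573). For those 3 lists the adjusted p was 0.325, 0.305 and 0.257 with an estimated correlation.

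In Kidney 4431 of 15706 genes passed at 30 months (2216 higher, 2215 lower), 1663 at 24 months (1053 higher, 610 lower) and 75 at 15 months (59 higher, 16 lower). Gpnmb was higher at each age, by 2.16, 3.10 and 3.40 in turn, and C4b stood at 2.25 and Cxcl13 at 3.77 at 24 months. The 30-month replicates 3 and 4 stood apart (median rank correlation 0.977 for each). Without both, 2692 genes passed at 30 months, 2693 at 24 and 329 at 15, and without replicate 3 alone the counts at 24 and 15 months were 2517 and 251. The 24-month count was 925 to 1098 without 6-month replicate 2 or 3 or 24-month replicate 3 or 4, and the 15-month count was 36 without 6-month replicate 2. Fits of the 2 ages alone gave 361, 2327 and 3250 genes at 15, 24 and 30 months, and limma-voom 261, 2918 and 4466.

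The Liver comparison showed lower male-typical genes, some higher female-typical genes and higher leukocyte genes, while no list call passed with an estimated correlation (smallest adjusted p = 0.21). Mup15 and Mup17, major urinary protein genes expressed mainly in males and close enough in sequence to share reads, fell (-7.33 ± 0.90, adjusted p = 0.00021, and -7.23 ± 0.86, 0.000198). Hsd3b5, a male-specific steroid enzyme, fell by 5.73 ± 1.17 (0.0027). Without 30-month replicate 3, which stood apart for both Mup genes, these 3 genes stood at -6.07, -6.04 and -3.90. Genes that are normally higher in females rose, with Cyp2b9 at 4.39 ± 0.98 (0.00464), Cyp2a4 at 4.28 ± 0.72 (0.00094) and Slc22a27 at 4.20 ± 0.34 (8.12e-06). Gpnmb rose by 5.54 ± 0.68 (0.000206), Lcn2 by 4.75 ± 1.16 (0.00784) and the T cell chemokine Ccl5 by 4.32 ± 0.77 (0.00128).

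Of 26 male-biased liver genes 22 fell in Liver (25 adjusted over the list alone, mean -2.86, camera adjusted p = 1.07e-13), and of 15 female-biased genes 7 rose (8, mean 1.80, 0.00189). Both had an adjusted p = 0.26 with an estimated correlation. Rises were counted for 14 of 18 plasma cell and immunoglobulin genes (15 adjusted over the list alone), 14 of 15 B cell genes (14), 17 of 20 T and NK cell genes (20), 20 of 22 macrophage genes (20) and 12 of 27 collagen genes (17, with 1 lower). Their camera adjusted p ran from 4.84e-13 to 2.43e-07 and their adjusted p from 0.21 to 0.238 with an estimated correlation. Falls were counted for 30 of 40 subunits of complexes I and II (39), 29 of 33 of complexes III to V (31), 21 of 32 proteasome genes (27) and 17 of 27 fatty acid oxidation genes (18, with 1 higher), including Sdha (-0.65), Uqcrc2 (-0.52), Psmd2 (-0.47) and Cpt2 (-0.64). For these lists camera's adjusted p ran from 2.26e-15 to 1.66e-07, and the adjusted p was 0.238 to 0.26 with an estimated correlation.

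In Liver 3408 of 14304 genes passed at 30 months (1939 higher, 1469 lower), 1556 at 24 months (1032 higher, 524 lower) and 164 at 15 months (92 higher, 72 lower). Igkc was 3.58 higher at 15 months, 4.60 at 24 and 4.15 at 30. Mup17 stood at -3.03 at 24 months (adjusted p = 0.0328). The 15-month count was 47 to 71 without 6-month replicate 1, 2 or 3 or 15-month replicate 2 or 3 and 109 without 6-month replicate 4. The 24-month count was 746 to 1003 without 6-month replicate 1 or 2 or 24-month replicate 1, 2 or 4. Fits of the 2 ages alone gave 467, 2504 and 2602 genes at 15, 24 and 30 months, and limma-voom 757, 2986 and 4119.

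The Lung comparison showed higher plasma cell, T cell and antigen presentation genes and lower genes of matrix, smooth muscle and alveolar epithelium, while no list call passed with an estimated correlation (smallest adjusted p = 0.34). Cd5l, a secreted protein of macrophages, rose by 5.84 ± 1.02 (adjusted p = 0.00147), the interferon-gamma induced chemokine Cxcl9 by 5.45 ± 0.63 (0.000106) and Ighg2c by 5.05 ± 0.73 (0.000433). Gzmk, a granzyme of T cells, rose by 4.28 ± 0.68 (0.000797). Aplnr (-2.37), its ligand gene Apln (-1.69) and Kdr, a receptor of vascular endothelial growth factor (-0.93), fell. Bpifb1, a secreted protein of airway epithelium, fell by 1.81.

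In Lung 14 of 20 plasma cell and immunoglobulin genes rose and 1 fell (16 and 1 adjusted over the list alone), 17 of 23 T and NK cell genes rose (20) and 19 of 22 antigen presentation genes rose (21), with camera adjusted p from 7.76e-14 to 3.95e-07. Fibrillar collagen genes fell in 15 of 28 cases (20, with 1 higher), basement membrane genes in 14 of 18 (15), smooth muscle genes in 11 of 18 with 1 higher (11 and 1), alveolar epithelium genes in 15 of 22 (16) and endothelial genes in 9 of 18 with 2 higher (10 and 2). Examples are Col6a3 (-0.99), Col4a1 (-0.46), Cnn1 (-1.27), Ager (-0.36) and Robo4 (-0.46). Camera's adjusted p for the lower lists ran from 3.59e-10 to 0.000285. All 8 calls were lost with an estimated correlation (adjusted p = 0.34 to 0.357).

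Lung had 3316 of 17112 genes past the threshold at 30 months (1837 higher, 1479 lower), 2591 at 24 months (1525 higher, 1066 lower) and 279 at 15 months (213 higher, 66 lower). Igkc was 2.23 higher at 15 months and 2.02 at 24, and Cxcl9 stood at 4.72 at 24 months. Fits of the 2 ages alone gave 648, 2878 and 2092 genes at 15, 24 and 30 months, and limma-voom 439, 3740 and 3279. The 30-month count was 2119 without 30-month replicate 4. The 24-month count was 1555 to 1669 without 6-month replicate 2 or 3 or 24-month replicate 2, and the 15-month count was 23 without 6-month replicate 4, 39 without 15-month replicate 2, 50 without 6-month replicate 2 and 100 to 139 without 6-month replicate 1 or 3 or 15-month replicate 1.

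The Muscle comparison showed higher expression of some genes that follow loss of nerve contact and lower expression of collagen genes, while no list call passed with an estimated correlation (smallest adjusted p = 0.27). Sln, sarcolipin, an inhibitor of the calcium pump, rose by 4.61 ± 0.64 (adjusted p = 0.000411), Myh3, embryonic myosin, by 2.61 ± 0.30 (8.51e-05), Chrnb1, a subunit of the acetylcholine receptor, by 1.04 ± 0.11 (3.94e-05) and Ankrd1, a stress-responsive muscle protein, by 2.20 ± 0.36 (0.00125). Krt18, an epithelial keratin, rose by 4.32 ± 0.58 (0.000295) and Cdkn1a by 2.13 ± 0.38 (0.00249). Col1a1 (-2.23), Col3a1 (-2.30) and Amd1, the decarboxylase that feeds polyamine synthesis (-2.12), fell, with the close copies of Amd1 Amd2 (-2.23) and Amd-ps3 (-2.24) able to share its reads.

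Of 22 denervation genes in Muscle 10 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 1.92e-09). Of 28 collagen genes 18 fell (20, 1.69e-11) and of 18 basement membrane genes 11 fell (13, 8.77e-10). All 3 had an adjusted p = 0.27 with an estimated correlation. Ribosomal protein genes rose in 48 of 74 cases (68 adjusted over the list alone, 1.6e-25), with Rpl3 at 0.82, and proteasome genes in 12 of 32 (21, 1.77e-10), with Psmd4 at 0.59. Macrophage genes rose in 14 of 22 (15), antigen presentation genes in 12 of 22 (14) and interferon genes in 15 of 29 (23), with camera adjusted p from 5.11e-11 to 9.82e-11. These 5 calls gave an adjusted p = 0.27 to 0.418 with an estimated correlation.

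In Muscle 1903 of 14545 genes passed at 30 months (895 higher, 1008 lower), 258 at 24 months (169 higher, 89 lower) and 88 at 15 months (59 higher, 29 lower). Ighg2c was higher at each age, by 2.10, 2.62 and 2.72, while Krt18 stood at 2.999 and Myh3 at 1.67 at 24 months. The 30-month replicate 3 library stood apart (median rank correlation 0.969), and without it the counts were 338 at 15, 772 at 24 and 1585 at 30 months. Without 6-month replicate 1, 2 or 3 the 30-month count was 1218, 1129 and 1142, and when the 2 ages alone were fitted the counts were 164 at 15, 1033 at 24 and 865 at 30 months (213, 1293 and 2294 with limma-voom). Leaving out any 1 library of the 2 ages moved the 15-month count to between 19 (without 6-month replicate 2) and 169 (without 15-month replicate 1), and without 6-month replicate 1, 2 or 3 or 24-month replicate 1, 2 or 4 the 24-month count was 69 to 118.

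The Aorta comparison was led by a fall of genes that respond quickly to stimuli, while no list call passed with an estimated correlation (smallest adjusted p = 0.425). Fosb, a transcription factor gene of the immediate early class, fell by 4.18 ± 0.60 (adjusted p = 0.00175), and Nr4a1 fell by 3.83 ± 0.69 (0.00595). Hspa1a and Hspa1b, inducible heat shock genes with near-identical sequences, fell (-3.90 ± 0.56, 0.00175, and -3.79 ± 0.57, 0.00206). Apold1, an endothelial gene also known as an immediate early gene, fell by 3.75 ± 0.35 (5e-05) and Nnat, an imprinted gene, fell by 3.39 ± 0.29 (3.44e-05). Elovl3, an elongase typical of brown fat, rose by 3.96 ± 0.67 (0.00461), Igfbp2 by 3.29 ± 0.29 (3.44e-05) and Ibsp, bone sialoprotein, by 2.80 ± 0.50 (0.0058).

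Immediate early genes in Aorta fell in 15 of 24 cases (23 adjusted over the list alone, mean -1.97, camera adjusted p = 9.25e-20) and cytosolic heat shock genes in 7 of 25 (9, mean -0.71, 8.22e-08). The adjusted p was 0.425 and 0.897 with an estimated correlation. Osteochondrogenic genes rose in 4 of 16 cases (7 adjusted over the list alone, 0.000396), with Mgp, an inhibitor of calcification, at 0.89 and Tnfrsf11b at 1.04. Fatty acid oxidation genes rose in 7 of 24 with 2 lower (8 and 2, 0.00137), lipogenesis genes in 4 of 20 (4, 0.000396) and clock genes in 4 of 18 (6, 0.0133), with Elovl6 at 1.53 and Ciart at 1.73. The call of Elovl6 (limma-trend adjusted p = 0.0268) was lost in 4 of 8 fits that left out 1 library (up to 0.0837). The adjusted p was 0.425 for the osteochondrogenic list and 0.897 for the other 3 with an estimated correlation. Markers of other cell types moved in the same comparison, with a median of 0.459 over 10 brown adipocyte genes (camera adjusted p = 0.00787, and 0.897 with an estimated correlation) and of 1.386 over 19 cardiomyocyte genes (0.245 and 0.912).

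Aorta had 850 of 15186 genes past the threshold at 30 months (462 higher, 388 lower), 884 at 24 months (428 higher, 456 lower) and 13 at 15 months (8 higher, 5 lower). Fosb stood at -3.63, Hspa1a at -4.11 and Igfbp2 at 2.87 at 24 months. The 15-month count was 6 by edgeR with RLE or TMM (3 higher, 3 lower), 299 by DESeq2 and 0 by limma-trend on those 2 ages alone, which gave 299 at 24 and 394 at 30 months (2192 genes had an unadjusted p under 0.05 in the fit of all ages), and another way of splitting those 8 libraries called 529. Leaving out 1 library gave 2 to 169 genes at 15 months (without 15-month replicates 3 and 2), 374 to 543 at 24 months without 6-month replicate 2 or any 1 of the 24-month libraries, and at 30 months 336, 533, 335, 298 and 472 without 6-month replicates 2 and 3 and 30-month replicates 1, 3 and 4.

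The Skin comparison showed lower levels of 3 non-coding RNAs of an imprinted cluster and of liver transcripts at 30 months, while no list call passed with an estimated correlation (smallest adjusted p = 0.651). The maternally expressed long non-coding RNAs Meg3, Rian and Mirg, which lie in a shared imprinted cluster, fell (-2.61 ± 0.25, adjusted p = 0.000226, -3.18 ± 0.36, 0.000938, and -3.15 ± 0.38, 0.00134). Col1a1 fell by 2.48 ± 0.40 (0.0162). Cdkn2a, which encodes the p16 and p19 tumour suppressors, rose by 3.07 ± 0.42 (0.0043), and Lce1g, a protein of the cornified envelope, by 1.70 ± 0.30 (0.0215). The call of Lce1g was lost in 3 of 8 fits that left out 1 library (adjusted p up to 0.0656), and that of Col1a1 in 3 of 8 (up to 0.0525). Liver transcripts were among those that fell, with Alb, albumin, at -5.07 ± 1.06 (0.0376) and Fga, a fibrinogen chain, at -5.31 ± 1.04 (0.0274). Both fell short when 1 library was left out, Alb without 6-month replicate 1 or 3 or any 1 of the 30-month libraries (adjusted p up to 0.112) and Fga without 6-month replicate 1 or 3 or 30-month replicate 2, 3 or 4 (up to 0.0971). Alb differed widely among the 6-month libraries, at 666.5, 3105, 10656 and 180.4 normalised reads, against 27.74 to 63.0 at 30 months.

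Of 23 hepatocyte synthesis genes tested in Skin 3 fell (21 adjusted over the list alone, mean -3.44, camera adjusted p = 1.03e-21). Of 28 collagen genes 1 fell (8, mean -0.73, 1.4e-08) and of 18 basement membrane genes 2 (4, 0.00114), with Col4a2 at -0.79. The call of Col4a2 (limma-trend adjusted p = 0.038) was lost in 6 of 8 fits that left out 1 library (up to 0.131). White adipocyte genes had a mean of -0.87 over 16 genes, 4 of them lower adjusted over the list alone (camera adjusted p = 3.03e-07). The adjusted p for these 4 lists was 0.651 to 0.706 with an estimated correlation.

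In Skin 122 of 16883 genes passed at 30 months (28 higher, 94 lower), 313 at 24 months (150 higher, 163 lower) and 29 at 15 months (27 higher, 2 lower). Cdkn2a was 4.37 higher at 15 and 3.34 at 24 months, and Meg3 stood at -2.02 at 24 months. Other ways of splitting the libraries of the 2 ages called up to 1798 genes at 24 months and 412 at 30, limma-voom called 0 at 15 months (2872 genes had an unadjusted p under 0.05 in limma-trend, and DESeq2 called 434), and fits of the 2 ages alone called 8, 40 and 45. Leaving out 1 library gave 12, 399, 32 and 61 genes at 30 months without 6-month replicates 1 to 4 and 57, 17 and 21 without 30-month replicates 2 to 4, 5 to 561 at 24 months (without 6-month replicate 1 and 24-month replicate 3) and 5 to 76 at 15 months (without 15-month replicates 3 and 4).

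Over all 8 tissues camera called 205 list changes at 30 months: 19 in Aorta, 26 in Brain, 31 in Heart, 34 in Kidney, 32 in Liver, 25 in Lung, 25 in Muscle and 13 in Skin. With an estimated correlation 21 passed, 8 in Brain, 10 in Heart and 3 in Kidney. In Heart these include the macrophage, lipid-laden macrophage and complement lists and in Kidney the tubule injury, p53 and reactive astrocyte lists. The last is the name of the list, and its call does not show astrocytes in Kidney.

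At 24 months camera called the antigen presentation list higher in 6 of the 8 tissues, of which Brain alone passed with an estimated correlation (adjusted p = 0.0068, and 0.115 to 0.277 in the other 5). In Aorta and Skin the list was not called (camera adjusted p = 0.145 and 0.725). Of 22 such genes 21 rose in Lung (21 adjusted over the list alone), 19 in Kidney (21), 15 in Liver (21), 10 in Muscle (20) and 9 in Heart (17), and of 21 tested in Brain 9 rose (18). Camera's adjusted p for these ran from 9.87e-35 to 1.73e-11. At 24 months camera called 20 lists in Aorta, 22 in Brain, 23 in Heart, 32 in Kidney, 26 in Liver, 23 in Lung, 18 in Muscle and 16 in Skin, of which 8 in Brain and 7 in Kidney passed with an estimated correlation. At 15 months it called 19, 22, 31, 32, 23, 27, 15 and 25 in the same order, of which 4 in Brain, 10 in Heart, 1 in Kidney and 1 in Muscle passed with an estimated correlation.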

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

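Of the tests in this part, those of white fat in a Heart library, of the excess of other tissues' transcripts in Skin, and of tissue composition and handling in Aorta were chosen after the result was seen. The others were set before their values were known. Among 64 groups of 4 libraries examined for depth and similarity, 7 had 1 library far from the other 3, and among 390 groups examined for the named genes, 30 did. The measure is the gap between an end library and its nearest neighbour over the whole range of the 4. Chance gives about 1 group in 20, so part of these groups is what chance gives.

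Heart 24-month replicate 4 stood apart in its median rank correlation with the other Heart libraries (gap over range 0.917). Low depth is argued against: the other 24-month Heart libraries, thinned to its reads, kept a median rank correlation of 0.981 to 0.986. Reads counted without strand met the condition set beforehand: 56 genes lying under exons of a far more abundant gene on the opposite strand had a median log2 ratio of 3.97 against the median of the other 15 libraries (quartiles 1.78 and 5.78, 45 genes over 1), with a floor of 1000 reads on the abundant gene added when the test was run. White fat in the sample stays open, with a median log2 ratio of 0.64 over 13 white adipocyte genes, 8 of them over 0, and so does a difference between animals, which was not tested, since the plasma cell list stood at 0.944, the cardiomyocyte list at -0.328 and Igkc at 6430 normalised reads against 18.16 to 431.7. A library counted without regard to strand is therefore a candidate explanation for part of the difference, beside which Gapdh stood at 15491 against 29706 to 38071 normalised reads, and Fam177a at 0 against 245.0 to 454.6 with Fam177a2 at 759.2 against 0 to 201.9.

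Hepatocyte transcripts were higher in 6-month than in 30-month Skin. Over 165 genes restricted to Liver, of which 146 were higher at 6 months and 4 of 62 tested fell, the excess in Skin followed the level in Liver with a rank correlation of 0.663, between the bounds set for and against RNA of liver in the Skin libraries, so that explanation stays open. RNA or reads of every other tissue met the condition set beforehand, with a ratio of 0.751, but that measure counts what Skin itself expresses (1.37% of the level of Brain transcripts against 0.355% of Liver's). The same ratio from the excess over 30-month Skin, added after 0.751 was seen, was -0.303 (-1.63 to -0.216 without 1 library), with an excess of 0.128% for Liver, 0.0592% for Brain, -0.0365% for Heart, -0.0413% for Kidney and -0.0617% for Lung, so the argument against reads of every other tissue rests on a test chosen afterwards. A change of Skin with age is confounded with the groups and was not tested, and Alb ranged from 180.4 to 10656 normalised reads at 6 months, 201.5 to 773.8 at 15, 43.83 to 830.0 at 24 and 27.74 to 63.0 at 30.

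Immediate early and heat shock genes were lower in 30-month than in 6-month Aorta. A change in the share of white fat and smooth muscle in the vessel samples is argued against: the larger of the median log2 changes of the white adipocyte and smooth muscle lists was 0.061 (quartiles -0.155 and 0.159 for smooth muscle, -0.14 and 0.13 for white fat), against -1.77 for the immediate early and -0.278 for the heat shock list. A change in the share of brown fat stays open, with a median of 0.459 over 10 brown adipocyte genes, 9 of them over 0, and that list, lipogenesis and fatty acid oxidation called higher (camera adjusted p = 0.00787, 0.000396 and 0.00137, and 0.897 for each with an estimated correlation). So does that of heart muscle, with a median of 1.386 over 19 cardiomyocyte genes, 17 of them over 0, and no call of the list (camera adjusted p = 0.245). Handling of the samples before freezing stays open: the immediate early list fell in 1 of the other 7 tissues (Brain) and the heat shock list in 5 (Brain, Heart, Kidney, Liver and Lung), but with an estimated correlation none of these calls passed (adjusted p 0.325 for the first and 0.157 to 0.675 for the others), nor did those in Aorta (0.425 and 0.897). Age and handling cannot be told apart here, because each Aorta group has 1 age and the labels give no time or order of dissection. A biological change with age is likewise open and was not tested.

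In depth, Aorta 30-month replicate 1 (gap over range 0.917), Brain 15-month replicate 4 (0.919), Liver 30-month replicate 4 (0.932) and Lung 24-month replicate 4 (0.905) stood apart from the other 3 libraries of their groups. In rank correlation the same held for Heart 6-month replicate 1 (0.974) and Skin 15-month replicate 3 (0.883).

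Among the named genes, 1 Aorta library stood apart for Elovl3 at 6 months (0.864, replicate 4), Col1a1 at 6 months (0.854, replicate 1) and Col3a1 at 30 months (0.902, replicate 2). In Brain this held for H2-Q7 at 30 months (0.868, replicate 4) and Fam181b at 6 months (0.873, replicate 2). In Heart it held for Zbp1 at 30 months (0.834, replicate 4), C4b at 6 months (0.839, replicate 1) and Scgb1c1 at 30 months (0.94, replicate 3). Kidney 30-month replicate 3 stood apart for Ugt1a2 (0.886), Slco1a1 (0.867), Ces1g (0.85) and Pzp (0.906), and 6-month Kidney libraries for Ighg1 (0.848, replicate 2) and Ighg2b (0.878, replicate 4).

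Liver 30-month replicate 3 stood apart for Mup15 (0.847) and Mup17 (0.919), and 6-month Liver libraries for Ighg1 (0.904, replicate 3) and Cd74 (0.923, replicate 1). At 6 months in Lung the genes were Saa3 (0.885, replicate 2), Cdkn1a (0.946, replicate 3) and C4b (0.863, replicate 1). Muscle 30-month replicate 3 stood apart for Amd1 (0.914), Amd-ps3 (0.839) and Cd74 (0.91), Muscle 6-month replicate 4 for Col1a1 (0.896), Col1a2 (0.915) and Cdkn1a (0.855), and other 6-month Muscle libraries for Amd-ps3 (0.846, replicate 3) and Jchain (0.901, replicate 1). In Skin B2m at 30 months had 1 library apart (0.859, replicate 1).

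The change from 6 to 30 months differed between tissues for 15 of 18 genes by the test of the difference itself (limma-trend F test, adjusted p). Among the genes shared by the most tissues the adjusted p was 0.00771 for Igkc, 0.0159 for Zbp1, 7.65e-14 for Gpnmb, 0.00287 for Ly9, 5.93e-06 for H2-Q6, 9.76e-06 for H2-Q7, 0.00139 for Ms4a6d, 0.000412 for Lilrb4b and 0.00482 for Apol9b. Among the other panel genes it was 0.000109 for Cdkn1a, 9.59e-06 for Cd74, 1.5e-06 for B2m, 2.51e-18 for C4b, 1.65e-09 for Col1a1 and 3.49e-07 for Col3a1. The sizes of change behind the smallest of these, C4b, ran from -0.31 in Aorta to 2.88 in Heart, and 9 of the 15 also passed with limma-voom and libraries of the same age and number as a block, where both the test and the block differ.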

How the results depend on the processing

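Of the settings in this part, edgeR with TMM, limma-trend on reads scaled by TMM and the pseudocounts for the gene counts were chosen after the data were seen. So were fits without libraries that stood apart, where these were of neither age compared or 2 were left out together. Leaving out 1 library for the shared genes and the genes that differ between tissues was also chosen afterwards. Leaving out each library of the 2 ages compared in turn was set before. Counts of genes past the threshold are compared with those of limma-trend on all 16 libraries of a tissue, at 15, 24 and 30 months: Aorta 13, 884, 850, Brain 4, 107, 1215, Heart 84, 703, 737, Kidney 75, 1663, 4431, Liver 164, 1556, 3408, Lung 279, 2591, 3316, Muscle 88, 258, 1903 and Skin 29, 313, 122. Values that moved by more than 1.5 times follow, and for each of them the cause was not tested unless it is named.

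With DESeq2 on recovered reads the count was for Aorta 299 at 15 months, 1570 at 24 months and 1589 at 30 months, Brain 34 at 15 months and 184 at 24 months and Heart 289 at 15 months, 1210 at 24 months and 1268 at 30 months. It was, further, Kidney 243 at 15 months, Liver 523 at 15 months and Lung 759 at 15 months. Last, it was Muscle 214 at 15 months and 506 at 24 months and Skin 434 at 15 months, 1109 at 24 months and 542 at 30 months. Limma-voom with quality weights gave for Aorta 4 at 15 months and 1530 at 30 months, Heart 745 at 15 months, 1229 at 24 months and 2181 at 30 months and Kidney 261 at 15 months and 2918 at 24 months. It was, further, Liver 757 at 15 months and 2986 at 24 months, Lung 439 at 15 months and Muscle 213 at 15 months and 1293 at 24 months. Last, it was Skin 0 at 15 months, 64 at 24 months and 1037 at 30 months. Without a filter, where more genes share the adjustment, the count was for Aorta 546 at 24 months and 550 at 30 months, Brain 1 at 15 months and Heart 460 at 24 months. It was, further, Liver 100 at 15 months and Muscle 166 at 24 months.

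With only the 2 ages compared, which leaves 8 libraries to estimate the spread, the count was for Aorta 0 at 15 months, 299 at 24 months and 394 at 30 months, Brain 2 at 15 months and 735 at 30 months and Heart 635 at 15 months, 99 at 24 months and 2100 at 30 months. It was, further, Kidney 361 at 15 months, Liver 467 at 15 months and 2504 at 24 months and Lung 648 at 15 months and 2092 at 30 months. Last, it was Muscle 164 at 15 months, 1033 at 24 months and 865 at 30 months and Skin 8 at 15 months, 40 at 24 months and 45 at 30 months. edgeR with RLE and edgeR with TMM both gave 6 genes in Aorta (3 higher, 3 lower, 50% higher against 61.5%) and 2 in Brain at 15 months. Beside the 0 of limma-voom in Skin and the 0 of the 2-age fit in Aorta at 15 months, 2872 and 2192 genes had an unadjusted p under 0.05 by limma-trend on all ages.

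Same-numbered libraries of a tissue come from different ages: their deviations correlated over 0.1 in 36 of 192 pairs, so the numbers were not taken to pair the libraries. Outside Skin the mean correlation was 0.028 to 0.0453 for the same number, against -0.00945 to -0.0151 for different numbers. In Skin it was -0.0549 against 0.0184, and none of these means was tested. With the replicate number as a block the count was 11 in Brain at 15 months and 13, 205 and 56 in Skin at 15, 24 and 30 months, and no other gene count moved by more than 1.5 times. Over all tissues, 330 genes passed in 4 or more tissues in place of 846 in 3 or more, by construction a stricter count. The other settings gave 875 with the block to 1177 with DESeq2. Camera called 205 lists at its preset correlation and 21 with an estimated correlation, 206 with the block, 205 with RLE and 207 with TMM, and fry called 173. Genes that differ between tissues numbered 6925 of 21683, 6954 with edgeR and TMM and 7099 with edgeR and RLE. They numbered 6528 with limma-voom and the block by age and number, where both the test and the block differ. Over the 11817 genes tested in all 8 tissues, a smaller set, they numbered 5131.

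Leaving out 1 library at a time gave the following lowest and highest counts, with age and replicate of the library left out, and after them the other libraries whose loss moved a count by more than 1.5 times, each from fewer samples. Aorta at 15 months: 2 (15 months, replicate 3) to 169 (15 months, replicate 2), then 71, 3, 8, 97 (6 months, replicates 1, 2, 3, 4) and 5 (15 months, replicate 4). Aorta at 24 months: 374 (24 months, replicate 3) to 945 (6 months, replicate 4), then 420 (6 months, replicate 2) and 543, 476, 396 (24 months, replicates 1, 2, 4). Aorta at 30 months: 298 (30 months, replicate 3) to 1156 (6 months, replicate 4), then 336, 533 (6 months, replicates 2, 3) and 335, 472 (30 months, replicates 1, 4). Brain at 15 months: 1 (15 months, replicate 3) to 7 (15 months, replicate 1), then 2, 1, 1 (6 months, replicates 1, 2, 3) and 2 (15 months, replicate 4). Brain at 24 months: 57 (24 months, replicate 1) to 101 (6 months, replicate 1), then 69 (6 months, replicate 4) and 69 (24 months, replicate 4). Brain at 30 months: 812 (30 months, replicate 4) to 1132 (30 months, replicate 1). Heart at 15 months: 35 (15 months, replicate 2) to 544 (24 months, replicate 4), then 46, 55, 51 (6 months, replicates 1, 2, 4) and 37 (15 months, replicate 4). Heart at 24 months: 358 (6 months, replicate 3) to 1157 (24 months, replicate 4), then 363, 396, 378 (6 months, replicates 1, 2, 4). Heart at 30 months: 378 (30 months, replicate 1) to 2209 (24 months, replicate 4), then 454 (6 months, replicate 3) and 452 (30 months, replicate 3). Kidney at 15 months: 36 (6 months, replicate 2) to 251 (30 months, replicate 3). Kidney at 24 months: 925 (24 months, replicate 3) to 2517 (30 months, replicate 3), then 1098, 966 (6 months, replicates 2, 3) and 987 (24 months, replicate 4). Kidney at 30 months: 3437 (6 months, replicate 3) to 4323 (30 months, replicate 1).

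Liver at 15 months: 47 (6 months, replicate 1) to 223 (15 months, replicate 1), then 63, 60, 109 (6 months, replicates 2, 3, 4) and 60, 71 (15 months, replicates 2, 3). Liver at 24 months: 746 (24 months, replicate 1) to 1637 (24 months, replicate 3), then 910, 1003 (6 months, replicates 1, 2) and 930, 944 (24 months, replicates 2, 4). Liver at 30 months: 2621 (6 months, replicate 1) to 3929 (30 months, replicate 4). Lung at 15 months: 23 (6 months, replicate 4) to 229 (15 months, replicate 3), then 100, 50, 139 (6 months, replicates 1, 2, 3) and 128, 39 (15 months, replicates 1, 2). Lung at 24 months: 1555 (24 months, replicate 2) to 2818 (6 months, replicate 1), then 1657, 1669 (6 months, replicates 2, 3). Lung at 30 months: 2119 (30 months, replicate 4) to 3797 (30 months, replicate 3). Muscle at 15 months: 19 (6 months, replicate 2) to 338 (30 months, replicate 3), then 20, 37, 33 (6 months, replicates 1, 3, 4) and 169, 29, 39, 26 (15 months, replicates 1, 2, 3, 4). Muscle at 24 months: 69 (6 months, replicate 3) to 772 (30 months, replicate 3), then 110, 115 (6 months, replicates 1, 2) and 118, 85, 118 (24 months, replicates 1, 2, 4). Muscle at 30 months: 1129 (6 months, replicate 2) to 2196 (30 months, replicate 2), then 1218, 1142 (6 months, replicates 1, 3). Skin at 15 months: 5 (15 months, replicate 3) to 76 (15 months, replicate 4), then 7, 11 (6 months, replicates 1, 2) and 45, 13 (15 months, replicates 1, 2). Skin at 24 months: 5 (6 months, replicate 1) to 561 (24 months, replicate 3), then 183 (6 months, replicate 3) and 19, 31, 204 (24 months, replicates 1, 2, 4). Skin at 30 months: 12 (6 months, replicate 1) to 399 (6 months, replicate 2), then 32, 61 (6 months, replicates 3, 4) and 57, 17, 21 (30 months, replicates 2, 3, 4).

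Leaving out 1 library of 6 or 30 months gave 747 (Lung, 30 months, replicate 4) to 898 (Lung, 30 months, replicate 3) shared genes. Genes that differ between tissues then numbered 6468 (Liver, 30 months, replicate 3) to 7301 (Skin, 6 months, replicate 2). Lists numbered 202 (Aorta, 6 months, replicate 1) to 220 (Skin, 6 months, replicate 2). Libraries of 15 and 24 months were not left out for these 3 results. Heart 24-month replicate 4 therefore stayed in, although without it the Heart count at 30 months was 2209 in place of 737. Without Kidney 30-month replicates 3 and 4 together the counts were 329, 2693 and 2692 at 15, 24 and 30 months, and without Muscle 30-month replicate 3 the count at 30 months was 1585.

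Of 716 pairs of a named gene and a tissue, 686 passed and 521 of them passed in every setting with a value. Over 13092 values, 12268 kept direction and side of the threshold, 753 fell short of it, 36 newly passed and 35 changed sign, the last in 11 pairs that did not pass. Aorta Cdkn1a (-0.02) was 0.021 with edgeR RLE, 0.023 with DESeq2, 0.018 with edgeR TMM and 0.04 with limma-voom, adjusted p 0.955 to 0.982. Brain Col1a1 (0.07) was -0.061 with limma-voom (adjusted p 0.913). Heart Col3a1 (-0.002) was 0.031 with edgeR RLE and DESeq2, 0.037 with edgeR TMM and 0.006 with limma-trend on TMM-scaled reads, adjusted p 0.96 to 0.996. Skin Gpnmb (0.16) was -0.20 with limma-voom (adjusted p 0.67). Without 1 library the values ran from -0.33 to 0.22 for Aorta Cdkn1a, -0.15 to 0.26 for Aorta B2m, -0.34 to 0.35 for Brain Cdkn1a and -0.11 to 0.18 for Brain Col1a1. They ran from -0.17 to 1.31 for Heart Jchain, -0.16 to 0.14 for Heart Col3a1, -0.061 to 0.75 for Kidney Col1a1 and -0.25 to 0.56 for Kidney Col3a1. In Skin they ran from -0.011 to 0.15 for Cdkn1a, -0.52 to 0.042 for C4b and -0.20 to 0.43 for Gpnmb. On simulated data with the levels and spread of each tissue, 14.9% to 71.6% of genes changed 1.5-fold were called, and depth was not varied.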

Other observations

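Of the tests in this part, those of libraries with the same age and number, and the same split in every tissue for the lists and for the genes that differ between tissues, were chosen after the result was seen, and the other splits of the libraries and the tests of transcript length were set before.

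Each comparison of 2 ages was set against all 35 splits of its 8 libraries into 4 and 4. Chance cannot be excluded by this count at 15 months in Aorta, where 6 of 35 splits called as many genes (13 genes in the real split, 529 in the highest other), or in Brain, where 3 did (4 and 195). The same holds for Skin at 24 months, where 3 splits did (313 and 1798), and at 30 months, where 2 did (122 and 412). In these 4 comparisons other splits called several times the real number, which points to a structure of the samples other than age.

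In the other comparisons the real split alone called the most genes, a share of 1 in 35. This is the smallest share that 35 splits can give, and it was not adjusted over the comparisons. Comparisons of the same tissue also share their youngest libraries. The share by itself therefore does not exclude chance, although the real number was far above that of any other split. Nor can the splits tell age from anything else that differed between whole age groups. The real number and the highest of the other splits were 884 and 13 in Aorta at 24 months and 850 and 1 at 30, and 107 and 1 in Brain at 24 and 1215 and 2 at 30. At 15, 24 and 30 months they were 84 and 0, 703 and 1, and 737 and 1 in Heart, 75 and 1, 1663 and 1, and 4431 and 0 in Kidney, and 164 and 1, 1556 and 1, and 3408 and 0 in Liver. They were 279 and 0, 2591 and 0, and 3316 and 201 in Lung, and 88 and 1, 258 and 0, and 1903 and 11 in Muscle, and 29 and 1 in Skin at 15 months. That Skin count ran from 5 to 76 when 1 library was left out.

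For the gene lists at 30 months chance cannot be excluded in Aorta (19 lists, 25 in the highest other split, 15 of 35 splits as high), Brain (26 and 26, 2 splits), Lung (25 and 29, 9 splits), Muscle (25 and 25, 2 splits) and Skin (13 and 31, 30 splits). With all 8 libraries the real split alone called the most lists in Heart, Kidney and Liver. The numbers there were 31 and 30 (1 split), 34 and 32 (1 split) and 32 and 31 (1 split). The margin was 1 or 2 lists, and 1 of 35 is the smallest share these splits can give, not adjusted over the 8 tissues. Chance is therefore not excluded by these margins. Without 1 library the real count was 28 to 31 in Heart, 32 to 36 in Kidney and 30 to 33 in Liver, and splits of the 7 libraries left were not run. With each tissue split by itself in 100 drawn splits, the real one alone reached 205 lists (highest other 176), 846 genes in 3 or more tissues (0) and 6925 genes that differ between tissues (3148). The same split of the numbers in every tissue keeps libraries of the same number together. There 1 of 35 splits reached 846 genes (highest other 0), 205 lists (195) and 6925 genes (724). That share is the smallest 35 splits can give. The real split was far from the others for the genes that differ between tissues, while for the lists the margin was 10 alone. For the shared genes the 0 follows largely from the few calls of mixed splits within tissues. At 30 months these called at most 0 genes in Kidney and Liver, 1 in Aorta and Heart, 2 in Brain and 11 in Muscle. The gap of 846 to 0 therefore gives no support for sharing beyond the counts within tissues.

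Libraries with the same age and number deviated together in different tissues. Over the 7 tissues other than Aorta the mean correlation of their deviations from the group means was 0.0508, against -0.0165 for libraries with different numbers, a difference of 0.0673 (permutation p = 1e-04, one-sided, the smallest that 10000 permutations can give, highest of them 0.0371). By age the difference was 0.0493, 0.0818, 0.0655 and 0.0724 at 6, 15, 24 and 30 months. For Aorta against the other 7 tissues it was 0.0317 (permutation p = 0.0345, one-sided, highest 0.0569). Outside Skin (-0.0549), libraries of a tissue with the same number at different ages, which cannot be 1 mouse, had mean correlations of 0.028 to 0.0453. The same mouse would not explain these means, which were not tested. A candidate explanation for the correlation across tissues is that the same mouse gave the libraries with the same age and number, while a shared order of processing predicts the same and cannot be told apart from it. The tissues are then not independent samples of animals.

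Longer transcripts falling with age was tested by the rank correlation between log2 fold change and transcript length. It was -0.146 in Aorta, 0.151 in Brain, -0.037 in Heart, 0.00383 in Kidney, 0.0918 in Liver, 0.0104 in Lung, -0.0432 in Muscle and -0.0688 in Skin. The number of the 35 splits with a value at least as far from 0 was 10, 15, 26, 35, 10, 34, 17 and 30 in the same order, so the hypothesis was borne out in none of the 8 tissues.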
